A study of Arabidopsis thaliana with 9 samples.

How the data were processed

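Above-ground parts of soil-grown Arabidopsis thaliana seedlings of 3 genotypes, wild-type Col-0 and the mutants cct-1 and gct-2, were profiled on Affymetrix expression arrays, 3 arrays per genotype. Per the labels' protocols plants grew at 23 °C with 16 h of light and 8 h of dark, and seedlings lacking cotyledons or leaf primordia were left out. Collection went round the 9 tubes in small lots to limit an effect of collection time, and cDNA was amplified from 50 ng of RNA. Genotype, replicate number and age (7 days for wild type, 9 days for mutants) were taken from the labels.

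The deposited values were probe set expression values, 1 column per array, and were used as deposited. Their log2 scale was read from the deposited values themselves, which lay between about 1 and 14 with nearly equal medians on all arrays. GCRMA and MAS5 are named, without a role or a version, per the submitters' processing notes, so which steps of background correction, normalization and filtering each performed is not given in the sources used here. The deposited table held 16863 probe sets, and how these were chosen from those on the array is not given in the sources used here. No pseudocount was applied.

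Tests were run in R 4.3.3 with limma 3.58.1. A probe set was tested when it lay above its array's 40th percentile on at least 3 arrays and was not 1 of the 37 control probe sets, which left 10395. The median of that percentile over arrays was 6.86 on the log2 scale. One linear model with a mean per genotype was fitted to all 9 arrays, so that the genotypes shared an estimate of the spread, and contrasts were tested with moderated statistics (lmFit and eBayes) and an F test over the 3 genotypes. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Fold changes are between mean log2 values. Lower bounds of folds set each value of the dimmer genotype that lay under its array's filter to that filter, since detection calls were not used here. They are ratios of means and make no allowance for the spread between arrays.

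Gene names came from the platform annotation, updated through a RefSeq gene table of the assembly TAIR10.1. Of the probe sets other than controls 9335 had 1 gene, 351 had several and 7140 had none in that table, and those with several or none were left unnamed. Gene identifiers of 9291 probe sets matched the RefSeq table and 44 did not. Of the tested probe sets 5492 (52.8%) carried 1 gene name, so statements on named genes cover about that share. The gene lists described below were covered far less, with 37 of their 433 genes tested. A gene with several probe sets was represented by the one with the highest mean.

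The genes named in the text were chosen by a rule fixed before the data were examined. For each mutant against wild type these were the 10 genes each way with the largest change among called probe sets whose 3 mutant arrays lay on one side of all 3 wild-type arrays, and the 5 each way between the mutants. To these came 18 genes named in any case and, from each gene list, up to 4 called members, members not called being given with their values only. The 28 gene lists (433 genes) covered Mediator, the seed program, flowering, growth, hormones, stress, tissue markers and reference genes. Lists with at least 3 members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives, and Benjamini-Hochberg adjustment over the lists. Single list members below the filter were taken from a fit with no filter.

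The fits were tested on simulated data made from the real means and spread of the 10395 probe sets with 200 changed. At a log2 change of 1, 89.6% of 67 changed probe sets were recovered for cct-1, 89.6% of 67 for gct-2 and 92.5% of 67 between the mutants. At a log2 change of 0.5 the shares were 50.7%, 58.2% and 35.8%, and at 2 they were 98.5%, 100% and 97% of 66. Of the probe sets called in the simulated comparisons 11 of 170, 12 of 177 and 7 of 157 were unchanged ones. Each simulated probe set was drawn independently, with the changes in 1 genotype. These shares need not hold for correlated genes or for another number of changed probe sets.

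Alternatives were no filter, a 60th percentile filter, quantile normalization, median centring, an intensity trend with robust variance, array weights, the replicate number as a block, leaving out probe sets whose identifiers end in _s_at or _x_at, leaving out each array in turn, fits of the 2 compared groups alone, a threshold of 0.01 and a 2-fold minimum, and for lists the mean of all probe sets of a gene. Differences between 3' and 5' control probe sets were compared with a 2-sided exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. For actin these differed between mutants and wild type by 0.0173 (exact p = 0.8) and -0.0673 (exact p = 0.3), for GAPDH by 0.0853 (exact p = 0.3) and 0.063 (exact p = 0.6), and for ubiquitin by -0.222 and -0.229 (exact p = 0.1 each), in cct-1 and gct-2. The ubiquitin values of the mutants did not overlap those of wild type (1.79 to 1.86, against 1.47 to 1.69 in cct-1 and 1.54 to 1.63 in gct-2). Whether this bears on the comparisons with wild type was not tested. Genomic coordinates were not used here.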

Results

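CCT and GCT encode MED12 and MED13, subunits of the CDK8 module, a detachable part of the Mediator complex that links transcription factors to RNA polymerase. The series asked how the seedling transcriptome of Arabidopsis thaliana differs when either subunit is mutated, in the setting of developmental phase transitions. Above-ground parts of seedlings, either Col-0 wild type or carrying the cct-1 or gct-2 mutation, were profiled on expression arrays, with 3 arrays per genotype and 9 in all. Per the labels the 3 arrays of a genotype were separate biological replicates, each a pool of 75 to 100 seedlings. Harvest was set by stage, when the first leaf primordia were 1 mm long. That stage was reached at 7 days in wild type and at 9 days in both mutants, so that a difference between wild type and a mutant cannot be told apart from an effect of 2 days of age.

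The values covered 16863 probe sets, of which 10395 passed the filter on dim signals and were tested. Array medians lay between 7.7 and 7.76 on the log2 scale. The number of arrays limits the precision, and the median standard error of a difference between genotypes was 0.111. Levels under the filter were not shown to be above background. In 17 of the 20 named genes of cct-1, 15 of 20 of gct-2 and 7 of 10 between the mutants the dimmer genotype lay under the filter on all 3 arrays. Folds of these genes are ratios of measured values whose size is uncertain, and lower bounds were taken, after the data were seen, with such levels raised to the filter. These bounds, written as at least, make no allowance for the spread between arrays. No probe set was named here for CCT or GCT, so the targeted genes could not be used to check the genotype labels. Of the 18 genes chosen in advance for their part in embryo maturation, phase change or the CDK8 module, 2 had a named probe set, SMZ and SNZ, and the other genes were not analysed here.

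Replicates of a genotype resembled each other more than arrays of different genotypes. Pearson's r across tested probe sets was 0.9739 to 0.9914 within a genotype, 0.9626 to 0.9736 between cct-1 and gct-2 arrays, and 0.9372 to 0.9567 between mutant and wild-type arrays. These correlations are across probe sets, which are not independent replicates. No pair of arrays held the same values throughout.

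**Figure D1:**
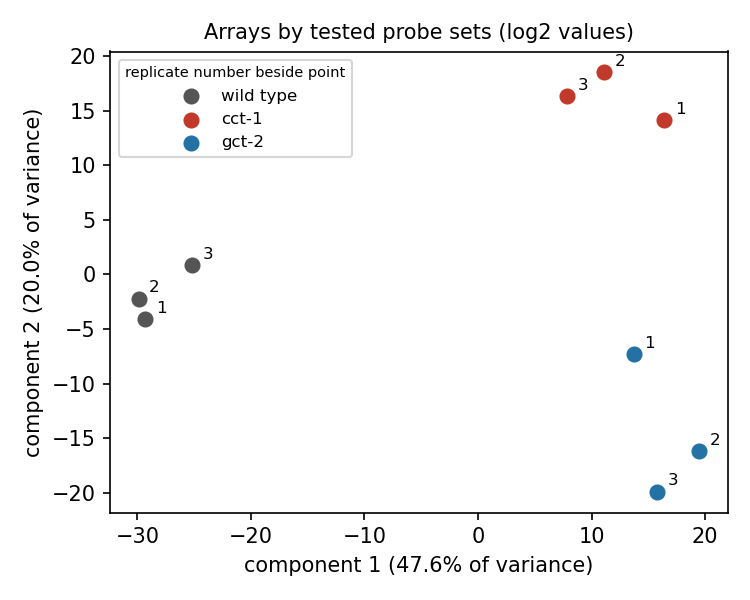
Principal components of the 10395 tested probe sets, with 1 point per array and the replicate number beside it. Component 1, with 47.6% of the variance, separated the 3 wild-type arrays from the 6 mutant arrays, and component 2, with 20% of the variance, separated cct-1 from gct-2.

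In cct-1 seedlings the thionin gene AT1G66100 fell from 10.87 ± 0.21 in wild type to 3.16 ± 0.43 (SD, n = 3 each), at least a 16.1-fold difference (209-fold as measured). AT3G16670 was at least 4.8-fold lower (128-fold as measured, log2 change -7.00, SE 0.26). As measured, the chitinase-family gene AT2G43590 was 23.2-fold lower (at least 1.22-fold), the copper amine oxidase genes AT1G31690 and AT3G43670 25.7-fold and 5.9-fold lower (at least 9.04 and 3.25-fold), the expansin gene EXPA16 14.6-fold lower (at least 2.54-fold) and the lectin-like gene AT3G16530 11.9-fold lower. AT1G12080, AT1G19380 and AT5G62360 were lower by 20.7, 7.04 and 6.3-fold as measured.

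Among the genes higher in cct-1, AT1G47540 rose from 2.37 ± 0.30 to 8.99 ± 1.49 (SD, n = 3 each), at least a 4.42-fold difference (98.4-fold as measured). As measured, the late embryogenesis abundant family gene AT3G02480 was 7.07-fold higher, the mitochondrial cytochrome c biogenesis gene ccb452 6.32-fold, AT1G47400, which encodes a small peptide of the iron-deficiency response, 4.8-fold, and the auxin-conjugating enzyme gene WES1 (GH3.5) 3.58-fold. AT5G42760 (4.57-fold), AT1G04660 (4.41-fold), AT3G56290 (4.34-fold), AT2G07718 (4.01-fold), a locus in the part of chromosome 2 that holds a copy of the mitochondrial genome, and the strictosidine synthase-like gene AT3G57020 (3.71-fold) completed the 10 largest measured increases. Those of AT1G04660 and WES1 had no lower bound above 1, while AT1G47400 and AT3G57020 lay above the filter throughout.

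With limma, 1344 of the 10395 tested probe sets (12.9%) were called in cct-1 against wild type at an adjusted p under 0.05, 655 of them higher and 689 lower, and 245 differed at least 2-fold. The adjusted p was 2.91e-06 for AT3G16670, 3.46e-05 for AT1G66100 and 0.0012 for AT1G47540. The number called was 853 without wild-type replicate 1, 590 without wild-type replicate 2 and 792 without cct-1 replicate 2. Of the 20 named genes 18 kept their call in each fit with 1 array left out in which they were still tested. Genes above the filter on the arrays of 1 genotype only dropped out of the test when 1 of those arrays was left out. AT1G66100, AT3G16670, AT2G43590 and EXPA16, among others, were tested in only 6 of 9 fits with 1 array left out, those that kept every wild-type array. The same held for ccb452 with the cct-1 arrays. The calls of AT3G02480 (adjusted p = 0.0375) and AT1G04660 (adjusted p = 0.0297) were lost in 6 of 9 and 5 of 6 such fits, reaching an adjusted p of 0.126 and 0.104 without wild-type replicate 2. That of AT3G02480 was also lost in a fit of the 2 groups alone (0.0767) and with an intensity trend and robust variance (0.0731).

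Gene lists fixed in advance were thinly covered, with 37 of 433 genes tested and 5 of 28 lists holding at least 3 tested genes. Of all 10395 tested probe sets, 3003 had an unadjusted p under 0.05 with limma in cct-1, 3258 in gct-2 and 2374 between the mutants. Counts in lists at that threshold, or adjusted over a short list alone, are to be read against these. In cct-1 the photosynthesis list had a median log2 change of -0.23 over 7 genes. PSAE-1 differed by -0.30, PSBW by -0.25, PSAN by -0.24 and LHCB4.2 by -0.23, and 0 of 7 genes passed over all probe sets with limma (4 at an unadjusted p under 0.05) against 4 of 7 lower when adjusted over the list alone. In the cell cycle list the Aurora kinase gene AUR2 fell (log2 change -0.45, SE 0.10), AUR1 differed by -0.32 and the replication licensing gene PRL (MCM7) by 0.10, and 2 of 3 genes were lower when adjusted over the list alone. In the shoot meristem and leaf polarity list YAB5 rose (log2 change 0.43, SE 0.10), whereas PHV differed by -0.05 and YAB3 by 0.01.

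None of the 5 lists was called in cct-1 with limma's camera, and 1 had an unadjusted p under 0.05. The adjusted p was 0.0634 for photosynthesis genes (adjusted p = 0.527 with an estimated correlation), 0.301 for the cell cycle list, 0.635 for meristem and polarity genes and 0.764 for both core Mediator subunits and reference genes. With fry, which asks whether a set's genes move on balance one way, the adjusted p of the photosynthesis list was 0.00829. With array weights 1 list was called, and 1 was called without cct-1 replicate 1. The call of YAB5 (adjusted p = 0.0235) was lost without wild-type replicate 2 (adjusted p = 0.0889), without cct-1 replicate 2 (0.0768) and in a fit of the 2 groups alone (0.0516). That of AUR2 (0.0217) was lost in 5 of 9 fits with 1 array left out, with an adjusted p of up to 0.076 without wild-type replicate 2.

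In gct-2 seedlings the same AT3G16670, AT1G66100, AT2G43590, AT1G12080, EXPA16 and AT1G31690 were among the 10 largest measured losses, at 126, 60.5, 26, 24.1, 17.9 and 14.1-fold lower as measured and at least 4.87, 16.3, 1.23, 2.79, 2.58 and 9.17-fold lower. The lipase-like gene AT5G33370 was at least 2.86-fold lower (28-fold as measured), falling from 8.36 ± 0.13 in wild type to 3.55 ± 0.46 (SD, n = 3 each). AT3G45160, AT1G29270 and CIL, whose product resembles a regulator of chloroplast protein import, were 6.09, 6.06 and 6.08-fold lower as measured. AT1G47540 was at least 6.63-fold higher (148-fold as measured, log2 change 7.21, SE 0.78), with an SD of 1.33 among gct-2 arrays.

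OASA2, annotated as an isoform of the cysteine synthesis enzyme O-acetylserine (thiol) lyase, rose in gct-2 by 9.36-fold as measured (at least 1.11-fold), from 3.77 ± 0.10 to 6.99 ± 0.14 (SD, n = 3 each). AT1G04660 (8.76-fold as measured, at least 1.44-fold), AT2G34700 (8.32-fold as measured, at least 1.21-fold), AT1G47400 (5.21-fold), the peroxidase gene AT2G37130 (4.43-fold) and the aspartic protease gene AT1G62290 (4.41-fold) were also higher. AT1G04660 and AT2G34700 were highest on the array of gct-2 replicate 2, at 8.75 and 8.85 against 6.31 and 5.55 on replicate 1 and 7.06 and 6.95 on replicate 3. On replicate 1 both lay under the filter of that array, 6.844. The TRAF-like genes AT1G65370 and AT5G26280 were higher by 3.69 and 3.6-fold and the pectinesterase gene AT1G05310 by 3.6-fold.

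With limma, 1586 probe sets (15.3%) were called in gct-2 against wild type, 778 higher and 808 lower, and 290 differed at least 2-fold. The adjusted p was 4.2e-07 for AT2G43590, 6.64e-06 for AT5G33370, 8.45e-05 for OASA2 and 0.000605 for AT1G47540. The number called was 805 without wild-type replicate 2, 902 without gct-2 replicate 2 and 1044 without gct-2 replicate 3. It was 2640 with no filter on dim probe sets and 2682 with array weights. The call of AT2G34700 (adjusted p = 0.0319) was lost without any 1 of the wild-type arrays, at up to 0.0862 without replicate 2, and with an intensity trend and robust variance (0.0538). The other 19 of the 20 named genes kept theirs in each fit with 1 array left out in which they were still tested. For AT5G33370 and AT2G43590, among others, these were only the 6 fits that kept every wild-type array. For OASA2 and AT1G05310 they were the 6 that kept every gct-2 array.

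The 3 tested cell cycle genes were all lower in gct-2, AUR1 by a log2 change of -0.42 (SE 0.11), AUR2 by -0.48 (SE 0.10) and PRL by -0.41 (SE 0.12). All 3 passed over all probe sets, and 3 of 3 when adjusted over the list alone. This was the list of the 5 that camera called (median log2 change -0.42, camera adjusted p = 0.0369 in limma; adjusted p = 0.395 with an estimated correlation). The camera adjusted p was 0.942 for the other lists, photosynthesis genes, meristem and polarity genes, core Mediator subunits and reference genes. In the photosynthesis list LHCB4.2 rose (log2 change 0.30, SE 0.07) and 1 of 7 genes passed both over all probe sets and when adjusted over the list alone. YAB5 rose (log2 change 0.36, SE 0.10), whereas PHV differed by -0.23 and YAB3 by -0.14. Signs differed within 3 lists: the photosynthesis list had a median of -0.0121, a mean of 0.00455 and an upward test, the meristem and polarity list a median of -0.141, a mean of -0.00208 and an upward test, and the core Mediator list a median of 0.00424, a mean of -0.00354 and a downward test.

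No list was called in gct-2 without wild-type replicate 1, cct-1 replicate 1 or gct-2 replicate 1, a count of 0 each, and with no filter the cell cycle list had an adjusted p of 0.051. The calls of AUR1 and PRL were lost in 6 and 7 of 9 fits with 1 array left out, at up to 0.109 without wild-type replicate 2 and 0.135 without gct-2 replicate 3, and that of AUR2 without wild-type replicate 2 (adjusted p = 0.052). The call of PRL was also lost with no filter (0.0543) and with quantile normalization (0.051). The calls of YAB5 and LHCB4.2 were lost in 4 and 5 such fits, at up to 0.129 without wild-type replicate 2 and 0.0722 without gct-2 replicate 2.

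Other listed genes were tested singly, since their lists held fewer than 3 tested genes. WES1 rose in both mutants (log2 change 1.84 in cct-1 and 1.64 in gct-2, SE 0.36 each). The gibberellin receptor gene GID1A rose in gct-2 (0.42, SE 0.07) and differed by 0.10 in cct-1. The cold-induced gene COR47 fell in cct-1 (-0.41, SE 0.10), a call lost in 4 of 9 fits with 1 array left out (adjusted p up to 0.113 without wild-type replicate 2) and in a fit of the 2 groups alone (0.0685), and differed by -0.03 in gct-2. COR15A, DFR, SDP1, LD, FY, AGL18, BZIP53 and the cyclin C loci AT5G48640 and AT5G48630 were called in neither mutant. COR15A differed by -0.45 and -0.20, DFR by 0.27 and -0.17, SDP1 by -0.11 and 0.18, LD by -0.05 and -0.16 and BZIP53 by -0.02 and -0.09 in cct-1 and gct-2. AT5G48640 differed by 0.19 and 0.23, AT5G48630 by 0.19 and 0.18, FY by 0.33 and 0.31 and AGL18 by 0.34 and 0.16. When adjusted over the list alone, 1 gene each of the autonomous flowering, embryo regulator and miR172-targeted lists passed in cct-1, and 1 of the miR172-targeted list in gct-2. These lists held only 2 tested genes each, so that adjustment corrects for little. The AP2-like floral repressor gene SMZ had log2 differences of 0.94 and 1.13 (SE 0.34, adjusted p = 0.0994 and 0.0524 with limma), which were called without wild-type replicate 1 (adjusted p = 0.0305 and 0.0151) and with array weights (0.0488 and 0.0163), and in gct-2 also with median centring (0.0455). SNZ differed by -0.08 and 0.07.

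**Figure D2:**
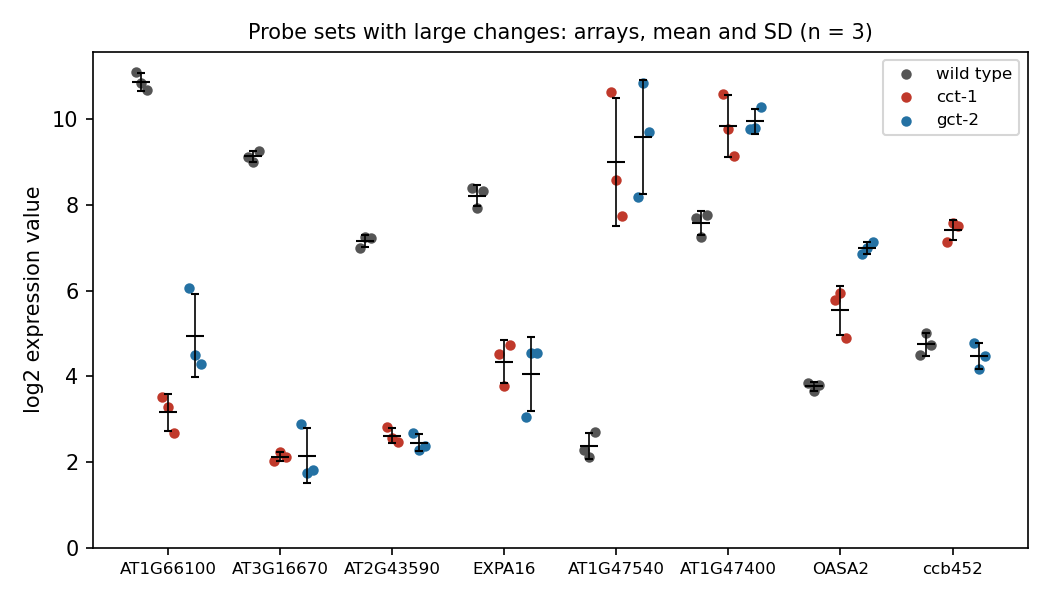
Log2 expression values of 8 genes with large changes on single arrays, with the mean and SD of 3 arrays per genotype. AT1G66100, AT3G16670, AT2G43590 and EXPA16 lay lower in all 6 mutant arrays than in wild type, AT1G47540 and AT1G47400 higher, OASA2 higher with its highest values in gct-2, and ccb452 higher in the 3 cct-1 arrays than in the other 6.

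Many calls against wild type were common to both mutants. Of the 31 genes with the largest changes named above for either mutant against wild type, 23 were called in the same direction in both, among them AT1G47400 (4.8 and 5.21-fold higher), AT1G47540, AT3G16670, AT2G43590 and EXPA16. The last 3 lay under the filter on all mutant arrays, so the mutants' folds for them cannot be compared in size. Over all tested probe sets 737 were called in the same direction, 332 higher and 405 lower, and 10 in opposite directions.

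The overlap expected of independent lists was 49 higher and 53.6 lower. The log2 changes had a Pearson's r of 0.759, a Spearman's rho of 0.607 and a covariance of 0.149 across probe sets. Both comparisons used the same wild-type arrays, and 100 simulated pairs of unchanged groups were set against shared controls. They gave a mean r of 0.429 (-0.892 to 0.95) and a mean rho of 0.418 (-0.803 to 0.921). Their mean covariance was 0.0129 (-0.0348 to 0.0724), with 0 shared calls with limma. The measured r and rho thus lay within the simulated ranges. The measured covariance lay above its range and exceeded the simulated mean by 0.136. The 3 controls were too few to be split, so part of the excess in the overlap may come from the shared controls. The number shared was 491 without wild-type replicate 1, 334 without wild-type replicate 2, 478 without gct-2 replicate 2 and 1173 with no filter.

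**Figure D3:**
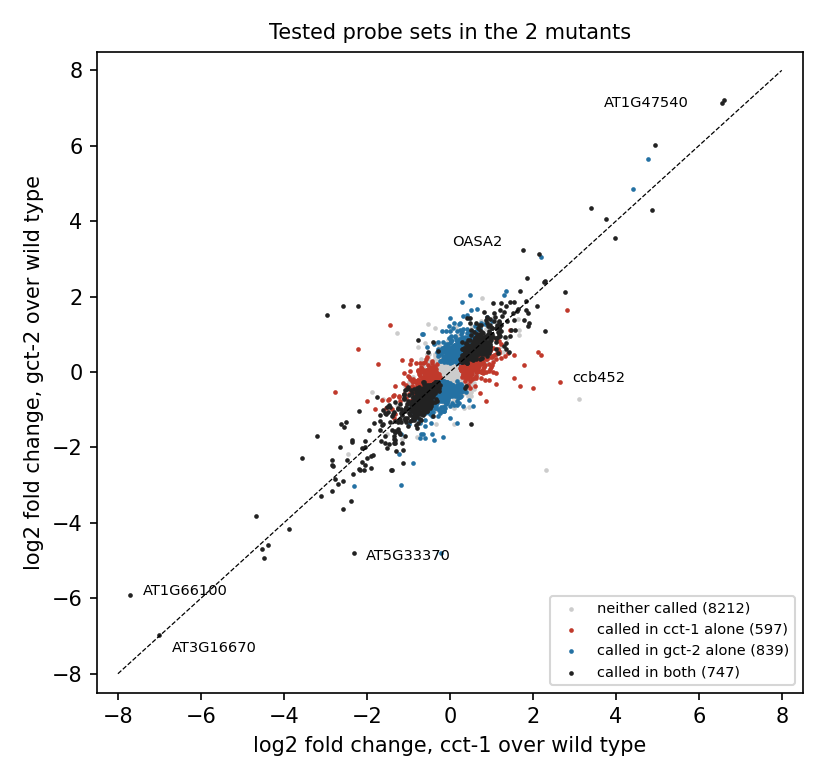
Log2 fold change of each tested probe set in cct-1 (horizontal axis) against gct-2 (vertical axis), coloured by the comparison in which it was called, with equal change on the dashed line. The 747 probe sets called in both lay mostly along that line, while 597 were called in cct-1 alone and 839 in gct-2 alone.

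The direct comparison of cct-1 with gct-2, both harvested at 9 days, asked where the mutants differ. As measured, the mitochondrial gene ccb452 was 7.65-fold higher in cct-1 (7.41 ± 0.23 against 4.47 ± 0.30, SD, n = 3 each), AT5G33370 5.63-fold (no lower bound above 1), AT2G07718 5.38-fold, AT3G28270 3.71-fold and AT5G42760 3.33-fold higher. The extensin-like gene AT2G15880 was 5.01-fold lower in cct-1, AT1G66100 3.45-fold (no lower bound above 1), the thionin gene THI2.2 3.16-fold, AT5G64180 3.08-fold and AT1G05310 2.95-fold lower. Photosynthesis genes were lower in cct-1 than in gct-2 as a list (median log2 difference -0.12 over 7 genes, camera adjusted p = 0.0305 in limma; adjusted p = 0.404 with an estimated correlation), with 1 gene passing over all probe sets, LHCB4.2 at -0.52 (SE 0.07), and 2 when adjusted over the list alone. With no filter that list had an adjusted p of 0.069. The other lists had an adjusted p of 0.371 (cell cycle), 0.405 (meristem and polarity genes, and reference genes) and 0.829 (core Mediator subunits). In the cell cycle list PRL was higher in cct-1 by 0.51 (SE 0.12), and GID1A was lower by -0.32 (SE 0.07).

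With limma, 664 probe sets (6.39%) differed between the mutants, 332 each way, and 83 at least 2-fold. The adjusted p was 0.000239 for ccb452, AT3G28270 and AT5G64180, and 0.000886 for AT5G33370. The count depended on single arrays: it was 391 without wild-type replicate 2, 400, 219 and 391 without cct-1 replicate 1, 2 or 3, and 184 and 151 without gct-2 replicate 2 or 3. It was 389 with the 2 mutants fitted alone, 358 with the replicate number as a block and 1023 with array weights. Of the 10 named genes 8 kept their call in each fit with 1 array left out in which they were still tested. For ccb452, AT2G07718 and AT5G42760 these were only the 6 fits that kept every cct-1 array. AT1G05310 was tested in the 6 that kept every gct-2 array and AT5G33370 in the 6 that kept every wild-type array. The call of AT1G66100 (adjusted p = 0.0383) was lost in 5 of 6 fits with 1 array left out, at up to 0.103 without cct-1 replicate 3, and in a fit of the 2 mutants alone (0.0807). That of AT2G15880 (0.0109) was lost without gct-2 replicate 3 (0.0535). The calls of PRL and GID1A were lost in 6 and 7 of 9 such fits, at up to 0.133 and 0.132 without gct-2 replicate 3, and with no filter (0.0529 and 0.0614) or in a fit of the 2 mutants alone (0.0672 and 0.0749). With an F test over the 3 genotypes 2050 probe sets differed; the count was 1055 without wild-type replicate 2, 1270 and 1325 without gct-2 replicate 2 or 3, and 3146 with array weights.

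Several fixed lists became measurable once dim probe sets were kept. The 4 seed storage and oil body genes with a probe set read higher on each of the 6 mutant arrays than on any wild-type array. Chance sets 6 of 9 arrays apart from the other 3, in either direction, for 2.38% of genes that do not differ by genotype. The share over all probe sets was not counted, and 12.9% and 15.3% of those tested were called in cct-1 and gct-2. The 4 genes varied together over the mutant arrays (r of 0.996 to 1 with their mean, genotype means removed), so they are not 4 independent observations. The vicilin-like storage protein gene PAP85 differed by a log2 change of 3.69 in cct-1 and 4.06 in gct-2 (SE 1.21), the related AT2G28490 by 2.96 and 3.62 (SE 1.08), the oleosin gene OLEO3 by 2.33 and 3.28 (SE 0.96) and the cupin gene AT4G36700 by 2.05 and 3.02 (SE 0.88). Levels varied widely between replicates, PAP85 lying at 7.81, 4.17 and 4.31 on the cct-1 arrays and at 3.55, 8.21 and 5.65 on the gct-2 arrays. The 4 genes were highest on the same arrays, those of cct-1 replicate 1 and gct-2 replicate 2. These arrays, picked out after their values were seen, were both the highest of their mutant for 1 of 6 late embryogenesis abundant genes, 8 of the 58 other listed genes (EEL and ICL among them) and 8.99% of all probe sets other than controls and the seed storage genes. They were so for 4 of the 17 genes named above as higher in a mutant, AT1G47540, AT1G04660, AT2G34700 and AT1G62290.

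With limma 0 of 4 passed in cct-1 over all probe sets (4 at an unadjusted p under 0.05) and 4 of 4 when adjusted over the list alone, and 2 of 4 and 4 of 4 did in gct-2 (OLEO3 and AT4G36700, adjusted p = 0.0498 and 0.0495). The camera adjusted p was 0.0865 in cct-1 and 0.0461 in gct-2 (adjusted p = 0.683 and 0.828 with an estimated correlation). The gct-2 call was lost without wild-type replicate 1 (adjusted p = 0.101), wild-type replicate 2 (0.0594) or gct-2 replicate 3 (0.0584), and a cct-1 call was gained without gct-2 replicate 2 (0.0346). The calls of OLEO3 and AT4G36700 were each lost in 7 of 9 fits with 1 array left out, at up to 0.122 without wild-type replicate 2 and 0.132 without gct-2 replicate 2, and with an intensity trend and robust variance (0.095 and 0.0946). With array weights PAP85 and AT2G28490 were called in gct-2 (0.018 and 0.0174).

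The 6 late embryogenesis abundant genes had median log2 changes of 0.91 and 1.07 in cct-1 and gct-2 (camera adjusted p = 0.227 and 0.182 in limma, the latter 0.0336 without gct-2 replicate 1), 0 of 6 passed over all probe sets or when adjusted over the list alone (2 and 1 at an unadjusted p under 0.05), and 1 of 6 was higher on each mutant array. AT3G17520 differed by 2.24 and 1.62 and LEA4-5 by 1.68 and 0.87. With array weights LEA4-5 was called in cct-1 (adjusted p = 0.0494) and AT5G44310, which differed by 0.37 and 1.26, in gct-2 (0.0415). AGL62, the 1 gene measured of the seed coat and endosperm markers, differed by 0.10 and -0.13, and ICL of the glyoxylate cycle by 1.02 and 0.85, none of them called.

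Of the 4 auxin genes measured with no filter, 1 rose and 1 fell in cct-1, and 2 rose and 1 fell in gct-2, with the same counts when adjusted over the list alone. GH3.3 read lower in both mutants (log2 change -0.94 and -1.63, SE 0.16, adjusted p = 0.00762 and 0.000412 with limma), while WES1, which encodes an enzyme of the same family, read higher. GH3.3 and IAA29 lay under the filter on all arrays, and WES1 on all wild-type arrays. Such levels were not shown to be above background, so the sizes of these changes are uncertain. IAA29 rose in gct-2 (1.26, SE 0.22, adjusted p = 0.00639) and differed by 0.25 in cct-1, and YUC4 differed by 0.28 and -0.01. The clock and photoperiod gene GI was lower in cct-1 (-1.92) and higher in gct-2 (1.75, SE 0.50 each, adjusted p = 0.0383 and 0.0443), calls lost in 6 and 7 of 9 fits with 1 array left out, at up to 0.101 without cct-1 replicate 3 and 0.131 without wild-type replicate 2, and in gct-2 with an intensity trend and robust variance (0.0566). GI lay under the filter on all wild-type and cct-1 arrays, so the size of its fall in cct-1 is uncertain. Of the other listed clock genes 0 had a named probe set. The auxin list had a camera adjusted p of 0.695 in cct-1 and 0.922 in gct-2. Embryo maturation regulators (0.611 and 0.922) and anthocyanin genes (0.611 and 0.343) were not called either. Of the 3 and 4 genes of the latter lists 0 passed over all probe sets with limma (1 of each list in cct-1, and 0 and 1 in gct-2, at an unadjusted p under 0.05), and AT5MAT, at -0.51 and -0.50 (adjusted p = 0.0657 and 0.057), was lower when adjusted over the list alone. Among 11 core Mediator genes AT1G23230 rose in cct-1 (0.61, SE 0.13, adjusted p = 0.0188), a call lost without wild-type replicates 1 and 2 (0.0555 and 0.0533) and without cct-1 replicate 2 (0.0597), and the list had a camera adjusted p of 0.842 and 0.922, with a median of -0.0166 and a mean of 0.0259 in cct-1.

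Other dim members were called in neither mutant. In cct-1 and gct-2 AGL24 differed by -0.18 and 0.05, GIS by -0.14 and -0.36, UF3GT by -0.48 and -0.40, AT4G14090 by 0.18 and -0.41, EEL by 0.33 and 0.21, GID1B by -0.07 and -0.26, PDF1.2 by 0.11 and 0.17 and WRKY53 by -0.32 and 0.37. TRY, a repressor of trichome fate, differed by 0.77 in cct-1 and -0.28 in gct-2 without being called over all probe sets, and passed in cct-1 when adjusted over the list alone. The lists of miR156-targeted SPL genes, FLC-clade repressors, Polycomb and embryo program repressors, heat shock, leaf ageing and root marker genes held no named probe set and were not analysed here.

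**Figure D4:**
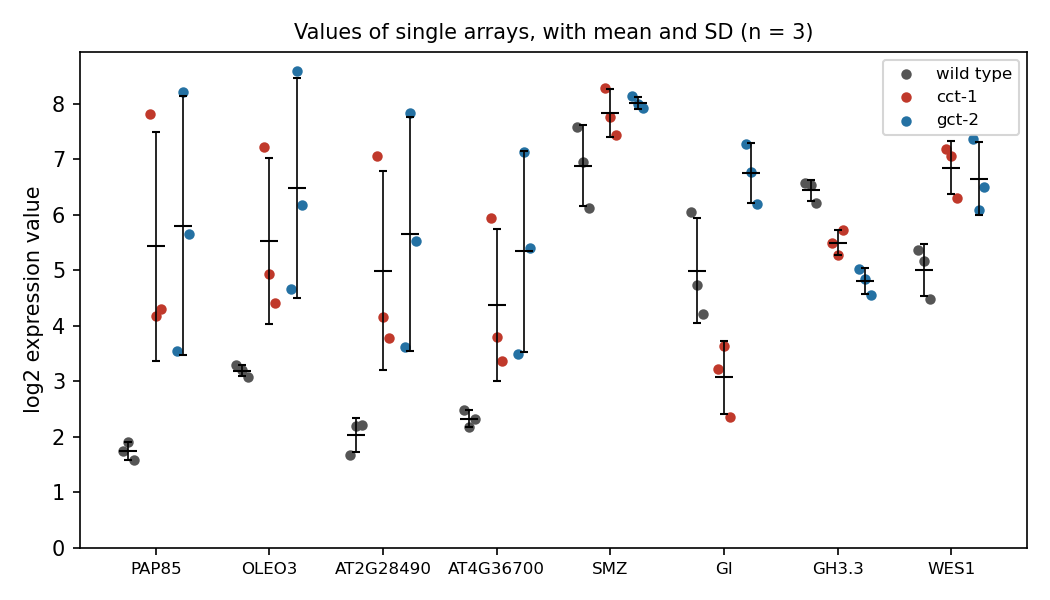
Log2 expression values on single arrays, with the mean and SD of 3 arrays per genotype, for 4 seed reserve genes (PAP85, OLEO3, AT2G28490, AT4G36700) and for SMZ, GI, GH3.3 and WES1. The seed reserve genes lay above wild type on each mutant array with a wide spread, and each GI value lay below all wild-type values in cct-1 and above all of them in gct-2.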

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

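The counts over other groupings of the arrays and the tests weighed below were chosen after the results were seen, except that of the dim probe sets. Each gene here was called by limma's test of cct-1 against gct-2. Values are measured log2 differences, cct-1 minus gct-2. Of the 24 genes 7 lay under the filter on all 6 mutant arrays, AT1G66100, AT3G16530, AT5G33370, CIL, TRY, IAA29 and GH3.3, so their levels there were not shown to be above background and the sizes of their differences are uncertain.

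Among genes higher in cct-1, the mitochondrial gene ccb452 differed by 2.94 (adjusted p = 0.000239), the lipase-like gene AT5G33370 by 2.49 (0.000886), AT2G07718 by 2.43 (0.00249), AT3G28270 by 1.89 (0.000239), AT5G42760 by 1.73 (0.00348) and AT3G56290 by 1.58 (0.00333). AT3G28270 was higher than wild type in cct-1 (a call lost in 4 of 9 fits with 1 array left out, at up to 0.0883 without wild-type replicate 2, and at 0.0505 in a fit of the 2 groups alone) and lower in gct-2, while AT5G33370 was lower in both. AT1G29270 differed by 1.2 (0.0401), CIL by 1.19 (0.0281) and PRL by 0.51 (0.0379).

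Among genes lower in cct-1, the extensin-like gene AT2G15880 differed by -2.32 (adjusted p = 0.0109), AT1G66100 by -1.79 (0.0383), the thionin gene THI2.2 by -1.66 (0.00367), AT5G64180 by -1.62 (0.000239), the pectinesterase gene AT1G05310 by -1.56 (0.00157), OASA2 by -1.45 (0.0118) and the lectin-like gene AT3G16530 by -1.30 (0.0424). AT3G43670 differed by -1.11 (0.0358), AT5G62360 by -0.66 (0.0424), LHCB4.2 by -0.52 (0.00665) and GID1A by -0.32 (0.0382). AT5G64180 was lower than wild type in cct-1 and higher in gct-2. Of the genes in both groups AT3G16530, AT5G62360, AT3G43670, AT1G29270, GID1A, PRL, AT1G66100 and CIL lost this call in at least 4 fits with 1 array left out, the highest adjusted p being 0.142 for AT5G62360 without gct-2 replicate 2, and AT2G15880 lost it in 1. With no filter it was lost by AT3G16530 (0.0537), AT5G62360 (0.0563), AT1G29270 (0.0512), PRL (0.0529) and GID1A (0.0614), and in a fit of the 2 mutants alone by these (0.064, 0.0591, 0.0749, 0.0672 and 0.0749), AT3G43670 (0.0737) and AT1G66100 (0.0807). GID1A also lost it with an intensity trend and robust variance (0.0591).

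Among dim probe sets GI differed by -3.67 (adjusted p = 0.00765), TRY by 1.05 (0.036), IAA29 by -1.01 (0.041) and GH3.3 by 0.69 (0.0496). The call of GI held without each array in turn, at up to 0.0334, while those of TRY, IAA29 and GH3.3 were lost in 7, 8 and 8 of 9 such fits, at up to 0.114, 0.0966 and 0.153, and that of GH3.3 with quantile normalization (0.055).

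GI was below wild type in cct-1 by -1.92 and above it in gct-2 by 1.75. It lay under the filter on 5 of the 6 mutant arrays and on all wild-type arrays (6.05, 4.73 and 4.21). Its fall in cct-1 is thus between levels not shown to be above background. Of the 4 unnamed probe sets called in opposite directions 3 had the signs of GI, at -2.22, -2.58 and -2.96 in cct-1 and 1.76, 1.74 and 1.52 in gct-2. So did the named AT5G64180, AT1G51610, AT1G19310 and AT2G46490, while AT3G28270 and AT4G30840 had the other signs. These probe sets were picked out after their values were seen. GI cycles over the day, so a difference in collection time could give this pattern, although the labels describe collection in turn over all tubes. Of the other clock genes listed 0 had a named probe set, so a shift in phase cannot be told apart from a change in GI. An effect of genotype also stays open.

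Of 18 mitochondrial probe sets 4 were called higher and 0 lower in cct-1 against wild type, with a camera adjusted p of 0.000492 with no filter (adjusted p = 0.111 with an estimated correlation), while with the filter the list was not called (1 of 7 higher, adjusted p = 0.118). An equal rise of all mitochondrial RNA would bring all 18 near the log2 change of 2.66 of ccb452, a gene picked for its large change. Their median was 0.163 with an error of 0.053, and that of the 7 that passed the filter was 0.158. This argues against an equal rise of that size for the 7, but not against a smaller or uneven one. The others were dim, so a rise there may not show. Transcripts of the AT2G07 loci, where a copy of the mitochondrial genome lies in chromosome 2, are another candidate source. Over 18 such loci the median was 0.384 (error 0.189), with 8 higher and 0 lower, and AT2G07741 (2.21) and AT2G07718 (2.00) led. The probe sets of AT2G07741, AT2G07718 and ccb452 had identifiers ending in _s_at, given to probe sets that can match more than 1 sequence. Such values cannot tell the copy from the organelle at any precision. Not every identifier of the AT2G07 loci ended so. Of the others AT2G07777 (1.203, adjusted p = 0.000938) and AT2G07705 (0.7466, adjusted p = 0.0122) were called higher in cct-1 by limma with no filter. AT2G07776 (0.3037), AT2G07724 (-0.02587) and AT2G07700 (-0.2005) were not called. These lay under the filter on all arrays, and whether they match the organelle too was not tested. An effect of genotype stays open.

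The 4 seed reserve genes read higher on all mutant arrays, with a camera adjusted p of 0.0865 in cct-1 (0 of 4 called with limma, 4 at an unadjusted p under 0.05) and 0.0461 in gct-2 (2 of 4 called; adjusted p = 0.683 and 0.828 with an estimated correlation). A lift of all dim probe sets would raise their median as well, but over 6431 dim probe sets it was 0.0282 in cct-1 and -0.00774 in gct-2, far below the medians of 2.65 and 3.45 of the 4 seed reserve genes. Seeds or late embryos in the mutant tubes could bring such transcripts, and the larger median of the late embryogenesis abundant list was 1.07. The 4 genes were highest on cct-1 replicate 1 and gct-2 replicate 2, as were AT3G01570 (7.39 and 7.94), AT4G21020 (4.99 and 5.37), AtLEA4-1 (5.75 and 5.86), EEL (6.86 and 6.6), ICL (4.99 and 4.41), AT1G47540 (10.64 and 10.84), AT1G04660 (6.9 and 8.75), AT2G34700 (7.66 and 8.85) and AT1G62290 (10.38 and 10.89), while the other 5 of 6 late embryogenesis abundant genes were not highest on both, nor was AT3G02480. EEL and ICL were among 8 of 58 other listed genes that were highest on both (13.8%, against 11.1% by chance). The photosynthesis genes PSAE-1, PSAN, PSBY and RCA were among those 8 too. No profile of seeds was at hand to set the lists against each other. Seeds or late embryos in the mutant tubes thus cannot be told apart from expression in the seedlings, and age stays confounded with genotype.

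Other splits of the arrays were counted. The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real value and the highest of the other splits were 967 and 0 for cct-1 against wild type, 1484 and 0 for gct-2 against wild type and 389 and 0 for cct-1 against gct-2. For gene lists they were 1 and 0 in gct-2, where 1 of 10 splits gave as many, and 0 and 1 in cct-1, where 10 of 10 did. Of 100 splits of the 9 arrays 1, the real one, gave as many as 2050 probe sets in the F test (highest other 728). For shared calls 1, again the real one, gave as many as 737 (highest other 450). These counts argue against arrays that do not differ by genotype at all. They cannot tell how many shared calls come from the wild-type arrays common to both comparisons, since the splits mix all genotypes.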

How the results depend on the processing

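Alternatives that combined no filter with a further choice were chosen after the data were seen, and the others before. Of 108 results for single genes, direction and side of the threshold were the same in 856 of 917 values under other settings, with 55 no longer called, 5 newly called and 1 turned. With 1 array left out they were the same in 676 of 846, with 165 no longer called, 2 newly called and 3 turned. The cause was not tested, except that a stricter threshold and a 2-fold minimum lower a count by construction. Signal over background was not measured here, which limits folds against dim levels. Standard errors of dim list members ran from 0.102 (AGL24) to 1.21 (PAP85).

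Probe sets called in cct-1 against wild type numbered 1344, against 502 at an adjusted p under 0.01, 245 with a 2-fold minimum and 590 to 1310 with 1 array left out. For gct-2 they numbered 1586, against 2640 with no filter, 2682 with array weights, 623 at 0.01, 290 with a 2-fold minimum and 805 to 1646 with 1 array left out. Between the mutants they numbered 664, against 1023 with array weights, 358 with the replicate number as a block, 389 in a fit of 2 groups, 123 at 0.01, 83 with a 2-fold minimum and 151 to 647. For any genotype difference they numbered 2050, against 3146 with array weights, 750 at 0.01, 366 with a 2-fold minimum and 1055 to 1939. Shared calls numbered 737, against 1173 with no filter, 290 at 0.01, 148 with a 2-fold minimum and 334 to 657.

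For gene lists in cct-1 0 were called with camera in limma (1 at an unadjusted p under 0.05), against 1 with array weights, 1 with fry and 0 to 1 with 1 array left out. In gct-2 1 was called, against 0 with an estimated correlation and 0 to 1 with 1 array left out. The log2 change of SNZ turned from -0.077 to 0.038 with array weights in cct-1 and ranged from -0.22 to 0.13 with 1 array left out, and from -0.078 to 0.27 in gct-2. With 1 array left out M17 ranged from -0.017 to 0.22 in cct-1 and -0.022 to 0.96 in gct-2, and AT3G15670 from -0.27 to 0.59 in gct-2. A pseudocount of 16 was not run, as the values were already on a log2 scale.

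Replicate numbers did not pair the samples. Deviations from the genotype means of arrays with the same number had correlations of -0.268 to 0.0881 over 9 pairs, 0 of them above 0.1, against -0.117 to 0.248 for 18 pairs of other numbers, 6 of them above 0.1. The highest were 0.248 for cct-1 replicate 2 with gct-2 replicate 1 and 0.221 for cct-1 replicate 1 with gct-2 replicate 2, the arrays on which the seed storage genes were highest. With the number as a replicate block 979 probe sets were called in cct-1, 1272 in gct-2, 358 between the mutants, 1455 for any difference and 554 in both. Of the 108 results for single genes 83 were the same under the block, 23 were no longer called and 2 were newly called.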

Other observations

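The tests of organelle genes and of gene families were chosen after their values were seen, and those of ribosomal protein, histone and further seed genes after the annotation was seen and before any fit. Cytosolic small-subunit ribosomal protein genes were slightly higher in cct-1 than in gct-2, with a median log2 difference of 0.139 over 36 genes (camera adjusted p = 8.15e-07 in limma; adjusted p = 0.303 with an estimated correlation). Against wild type the median was 0.117 in cct-1 (adjusted p = 0.00216, or adjusted p = 0.452 with an estimated correlation) and -0.0463 in gct-2 (adjusted p = 0.426), with 1 of 36 genes passing in cct-1, AT3G57490 (adjusted p = 0.0493), a call lost in 7 of 9 fits with 1 array left out, at up to 0.148 without wild-type replicate 2, and with no filter (0.0588). Single genes seldom passed, 2 of 36 between the mutants and 8 when adjusted over the list alone, AT3G60770 by 0.38 and AT5G58420 by 0.32, and both calls were lost in most fits with 1 array left out (8 and 6 of 9, adjusted p up to 0.154 and 0.122 without gct-2 replicate 3), with no filter (0.0647 and 0.056) and in a fit of the 2 mutants alone (0.0817 and 0.0727). Plastid-encoded genes had a median of -0.143 over 63 genes in cct-1 (adjusted p = 0.000758, or adjusted p = 0.486 with an estimated correlation) and of -0.097 in gct-2 (adjusted p = 0.191). Single genes did not follow these list tests, with 1 of 63 lower in cct-1 (rbcL) and 4 of 63 in gct-2 (rbcL, psbE, petA and petD). Adjusted over the list alone, 1 was lower in cct-1 and 0 in gct-2. Between the mutants the list had a camera adjusted p of 0.122, and psbH, psbI and psbN were lower in cct-1. Those 3 calls were lost in 6, 6 and 3 of 9 fits with 1 array left out. The gct-2 calls of psbE, petA and petD were lost in 4, 6 and 6 of 9 fits with 1 array left out, at up to 0.0663 without gct-2 replicate 2 for psbE and 0.119 and 0.142 without wild-type replicate 2 for petA and petD, and that of petD in a fit of the 2 groups alone (0.0684). The Rubisco large-subunit gene rbcL fell by 0.76 on the log2 scale in cct-1 and by 0.64 in gct-2, calls lost without wild-type replicate 2 (adjusted p = 0.0571 and 0.0835), and in gct-2 in 4 of 9 such fits.

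The core histone list, whose measured members were all H2B genes, had medians of -0.274 in cct-1 and -0.376 in gct-2 over 7 genes (camera adjusted p = 0.118 and 0.0513 in limma; adjusted p = 0.486 and 0.485 with an estimated correlation), with 2 of 7 lower over all probe sets in each mutant, and 3 and 4 of 7 when adjusted over the list alone. AT2G37470 fell by 0.35 and 0.41 on the log2 scale, AT2G28720 fell by 1.35 in cct-1 and AT3G53650 fell by 0.90 in gct-2. The cct-1 call of AT2G37470 was lost in 5 of 9 fits with 1 array left out (adjusted p up to 0.0687 without cct-1 replicate 1). With no filter the H2B genes were called as a list in both mutants, with medians of -0.348 and -0.407 over 9 genes (adjusted p = 0.00615 and 0.00391; adjusted p = 0.263 and 0.349 with an estimated correlation) and 3 genes lower in each. With no filter, mitochondrially encoded genes were higher in cct-1 than in gct-2 by a median of 0.372 over 18 genes (adjusted p = 4.73e-09, and adjusted p = 0.0115 with an estimated correlation), 3 of them passing over all probe sets and 10 when adjusted over the list alone. With the filter this median was 0.343 over 7 genes (adjusted p = 0.000864, or adjusted p = 0.131 with an estimated correlation). Further seed maturation genes, 3 of them and all dim, had medians of 1.44 and 1.45 in cct-1 and gct-2 (adjusted p = 0.0842 and 0.127), with 0 passing over all probe sets in limma (1 and 2 at an unadjusted p under 0.05) and 2 of 3 when adjusted over the list alone in gct-2. AT3G01570 and AT4G21020 were highest on cct-1 replicate 1 (7.39 and 4.99) and gct-2 replicate 2 (7.94 and 5.37), as the seed storage genes were. SAUR genes held no named probe set and were not analysed here.

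Of 13 families of genes that share the stem of a symbol, 0 were called with camera in limma in any comparison, while 3, 3 and 1 had an unadjusted p under 0.05 in cct-1, gct-2 and between the mutants. The lowest adjusted p was 0.0513, for CYP genes in gct-2 (median 0.546 over 7 genes). Apart from AT5G64180 and AT3G28270, 4 named genes were called in opposite directions in the mutants, AT4G30840 (0.38 in cct-1 and -0.38 in gct-2), AT1G51610 (-0.29 and 0.57), AT1G19310 (-0.41 and 0.81) and AT2G46490 (-0.53 and 0.53).

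The control probe set for 25S ribosomal RNA read 6.99, 7.29 and 7.12 on the wild-type arrays, 5.65, 5.94 and 6.8 on the cct-1 arrays and 5.62, 6.26 and 5.97 on the gct-2 arrays. That for 5S ribosomal RNA read 5.66 and 3.89 on the arrays of cct-1 replicates 1 and 2 and between 1.41 and 2.22 on the other arrays.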
